A study of Mus musculus with 8 samples.

How the data were processed

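Gastrocnemius muscle of 4 knockout and 4 wild-type mice was profiled on Affymetrix whole-transcript arrays. Per the labels' protocols, the snap-frozen muscle gave total RNA by Trizol and column clean-up, of which 100 ng was amplified, and 5500 ng of cDNA was fragmented and labelled. The authors deposited 1 table of log2 expression values, made with RMA in Affymetrix Expression Console per the submitters' processing notes; RMA corrects background, normalizes arrays by quantiles and summarises probes. Its settings, the software version and the array's genome build were not given in the sources used here, so no coordinates are given. RMA compresses differences of dim transcripts, and summarising many probes into 1 value per transcript cluster can leave signal when only some exons are lost.

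Groups came from the genotype in the labels, with 1 array per animal. The Cre transgene was present in knockouts alone, so its own effects and those of the deletion cannot be told apart. The deposited table held 35556 transcript clusters. The array annotation listed 23410 of them, 21789 with 1 gene symbol and 1621 with several, and 12146 were unnamed here. Of those with 1 gene, 21698 matched a GRCm38.p6 RefSeq gene table by Entrez number, and 0 symbols needed an update. Clusters with 1 gene were used, and a gene with several clusters (999 genes) was represented by the one with the highest mean over the 8 arrays, which left 19938 genes with no filter on dim ones. Other clusters of Irf1, Rps9 and Zfp706 had differences near 0 or of the opposite sign. Array medians lay between 4.61 and 4.72 and values between 0.754 and 13.2.

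Knockout and wild type were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 6 residual and 6.26 prior degrees of freedom, and the median SE of a difference was 0.105 log2 units (0.0858 at the 10th and 0.144 at the 90th percentile). Differences are knockout minus wild type. An exact two-sided permutation test of 4 against 4 values can give no p below 0.0286. Gene lists were tested with limma's camera (preset correlation 0.01), camera with an estimated correlation and fry, adjusted over 44 lists. They covered the dystrophin complex, Gcn5 complexes, energy metabolism, fibre types, muscle structure, stress and growth pathways and markers of other cell types, and 984 of their 1073 entries (942 distinct genes) were measured. Within each list, p values were also adjusted over the list alone.

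The comparisons, lists, alternatives and rule for named genes were fixed before the data were examined. The rule took Kat2a; up to 12 genes per direction past the threshold with separated groups, filled up to 8 by smallest p; up to 4 members past the threshold or otherwise 2 with the smallest p from each list; Dmd, Utrn, Dag1 and the sarcoglycans; and Kat2b, Ppargc1a and Yy1. Nr4a1, Nr4a2, Myc and Hspb1 fall outside it and were named because they passed within their list. Alternatives were other normalizations (quantile, median centring, cyclic loess), leaving out the dimmest 25% or 50% of genes, the mean over clusters, an intensity trend with a robust prior, array weights, the replicate number as a block, leaving out each array, all deposited clusters, other thresholds, limma's treat against a fold of 1.2 and other set tests. Leaving out wild type 2 and knockout 4 together, and covariates for slow-fibre and macrophage levels, were added after the data were seen.

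The limma steps were tested on simulated data with 200 changed genes in 20 simulations of this comparison over 19938 genes. They called 51.0% of genes changed by 0.5 log2 units, 94.7% of those changed by 1 and 99.5% of those changed by 2, and 5.06% of calls were unchanged genes. With 200 changed genes the adjusted threshold is easier to pass than where few genes change. The real comparison called 3 genes, so these shares do not give its power. There, Npnt at -1.03 and Actc1 at 1.79 missed the threshold. Every list shifted by 0.15 was called, but the simulated genes were independent, so that part does not test camera on correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.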

Results

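Gene expression was measured in the gastrocnemius, a mixed calf muscle, of 8 male mice. Kat2a encodes Gcn5, the lysine acetyltransferase of the SAGA and ATAC coactivator complexes. In 4 animals the floxed Kat2a gene was recombined by Cre under the human skeletal actin promoter, which acts in muscle fibres (knockout), and 4 animals carried the floxed gene without Cre (wild type). The mice were 6 months old, ate a chow diet and were fasted for 5 h. Each animal gave 1 Affymetrix array, and the number of arrays limits the precision. Array medians lay between 4.61 and 4.72 on the log2 scale. Wild type 2 had the lowest mean correlation with the other arrays (0.987) and lay at 32.2 on a first principal component that held 29.8% of the variance. Knockout 4 lay at -20.0 and wild type 4 at 20.9 on the second component (21.0%).

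The comparison asks which transcripts of resting, fasted muscle differ when muscle fibres lack Gcn5. Kat2a itself measured 6.46 ± 0.03 in wild type and 5.79 ± 0.05 in knockout muscle (log2, SD, n = 4 each), and was lower in each of the 4 knockouts than in every wild type. The difference was -0.66 (SE 0.08, limma adjusted p = 0.0319), or 0.631 of the wild-type level. Whether the probes of this transcript cluster lie in the recombined exons is not known here, and cells other than muscle fibres keep the gene, so the remaining signal does not measure the efficiency of recombination. The paralog Kat2b, which encodes the acetyltransferase PCAF, measured 6.43 ± 0.13 in wild type and 6.31 ± 0.06 in knockout (limma adjusted p = 0.880).

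Besides Kat2a, 2 of the 19938 genes passed a 5% false discovery rate. Lrtm1, which encodes a leucine-rich repeat transmembrane protein, rose from 6.76 ± 0.39 to 8.25 ± 0.31 (difference 1.49, SE 0.19, 2.80-fold, limma adjusted p = 0.0425). Ssbp2, a single-stranded DNA-binding protein that takes part in LIM-domain transcription complexes, fell from 8.29 ± 0.14 to 7.60 ± 0.08 (difference -0.69, SE 0.09, limma adjusted p = 0.0498). Both genes separated all 4 knockouts from all 4 wild types. In all, 1 gene was higher and 2 were lower at this threshold; after quantile or cyclic loess normalization 1 was higher and 1 lower, since Ssbp2 no longer passed. All 3 calls were lost without wild type 3, wild type 4 or any 1 of the knockouts, with Kat2a at limma adjusted p values from 0.0619 to 0.137, and Ssbp2 was also lost without wild type 1 or wild type 2. Over the same 8 refits the Kat2a difference stayed between -0.68 and -0.64.

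**Figure D1:**
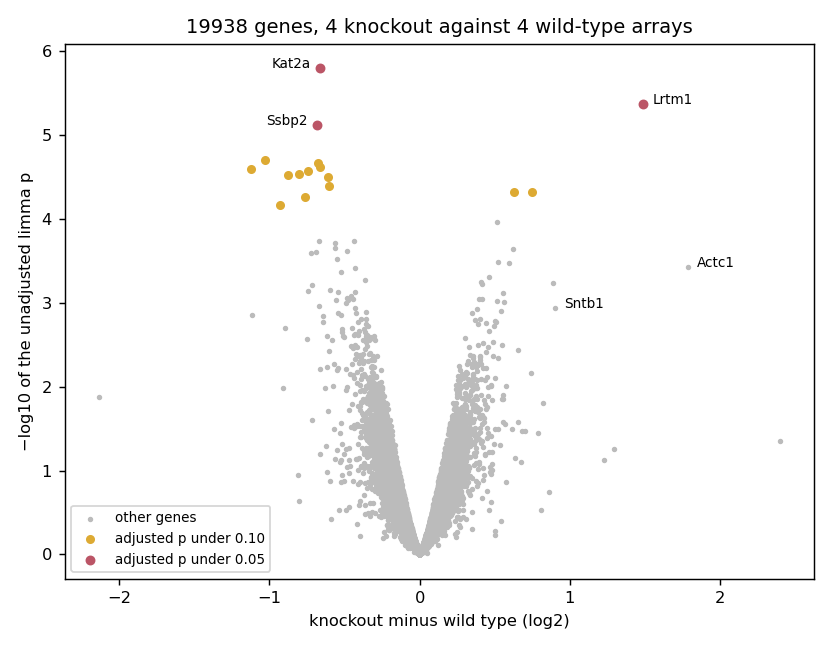
Each point is 1 of 19938 genes, with the knockout minus wild-type difference in log2 units on the horizontal axis and the negative log10 of the unadjusted limma p on the vertical axis. Red points are the 3 genes with an adjusted p under 0.05 (Kat2a and Ssbp2 lower, Lrtm1 higher), and yellow points are the other genes under 0.10.

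A further group of genes lay just short of the threshold. At a 10% false discovery rate 3 genes were higher and 13 lower. This count of 16 fell to 12, 2, 7 and 0 without wild types 1 to 4 and to 0, 4, 0 and 5 without knockouts 1 to 4. Among the lower genes, the limma adjusted p was 0.0568 for Npnt, Jun, Stk26, Ppp1r14bl, Itga4, Ctnna3 and Dmd. Npnt, which encodes the extracellular matrix protein nephronectin, measured 7.26 ± 0.21 in wild type and 6.23 ± 0.32 in knockout (difference -1.03). Itga4, the integrin alpha 4 chain, differed by -0.75 and Ctnna3, which encodes alpha-T-catenin of cell junctions, by -0.80. Ppp1r14bl differed by -1.12 and the kinase gene Stk26 by -0.66. Among higher genes, Plin3, which encodes a lipid droplet coat protein, measured 6.72 ± 0.15 in wild type and 7.34 ± 0.12 in knockout (difference 0.62, limma adjusted p = 0.0674). Ppp1r1a, an inhibitor of protein phosphatase 1, differed by 0.75 with the same adjusted p. Cntfr, a receptor chain for ciliary neurotrophic factor, differed by 0.52 (limma adjusted p = 0.128). Pcbd1, Hpgds and Vmn1r58 differed by 0.62, 0.52 and 0.59 with limma adjusted p values of 0.205, 0.238 and 0.238; Vmn1r58 measured only 2.12 and 2.71, near the bottom of the array's range.

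Actc1, the cardiac alpha actin that is also made in developing and regenerating skeletal muscle, had the widest difference among the named genes, 8.41 ± 0.64 in wild type and 10.19 ± 0.81 in knockout. Its difference of 1.79 (SE 0.37) did not pass over all genes (limma adjusted p = 0.258). At an unadjusted p under 0.05 there were 1142 genes, 467 higher and 675 lower, against 997 that chance gives. The groups did not overlap for 3.62% of genes, and chance gives 2.86%.

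**Figure D2:**
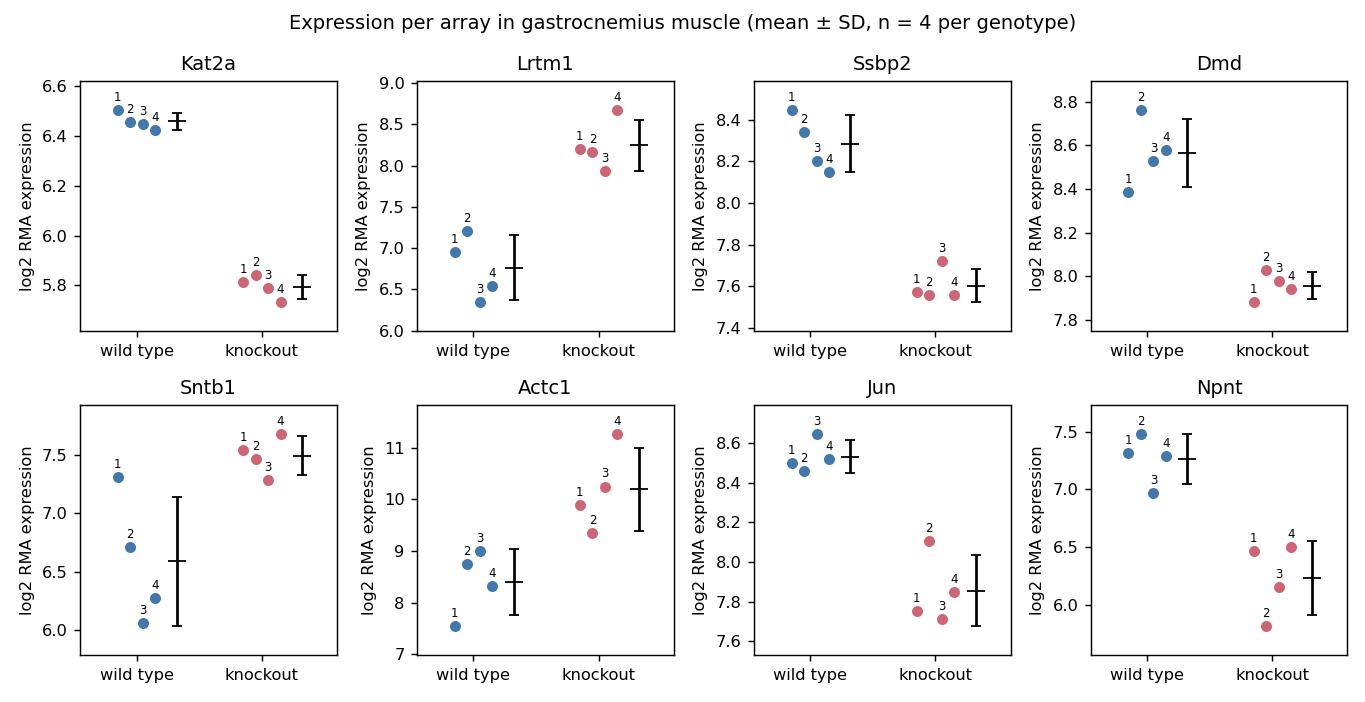
Log2 RMA expression of 8 genes in each array, with blue points for wild type, red points for knockout, the replicate number above each point and bars for mean ± SD (n = 4 each). Kat2a, Ssbp2, Dmd, Jun and Npnt lie lower in every knockout than in every wild type, and Lrtm1 and Actc1 lie higher. Vertical axes differ between panels and do not start at 0.

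Dystrophin, the protein encoded by Dmd, links the cytoskeleton of the fibre to a membrane complex that binds the extracellular matrix. Dmd measured 8.56 ± 0.16 in wild type and 7.96 ± 0.06 in knockout, and was lower in all 4 knockouts than in all 4 wild types (difference -0.61, SE 0.10, limma adjusted p = 0.0568). It passed in 3 of 20 alternatives and in 0 of the 8 that left out 1 array (limma adjusted p from 0.0597 to 0.264). Of the 21 measured members of the dystrophin complex list, 0 passed over all genes, and 2 passed adjusted over the list alone, Dmd at 0.000658 and Sntb1, which encodes the adaptor beta-1-syntrophin, at 0.0123. Those members went opposite ways, since Sntb1 measured 6.59 ± 0.55 in wild type and 7.49 ± 0.17 in knockout (difference 0.90). The list was written with knowledge that a publication on mice lacking Gcn5 in muscle concerns dystrophin, so these counts are not independent evidence. As a whole it did not pass in one direction (14 of 21 lower, mean -0.03, camera adjusted p = 0.349; mean 0.00755 without wild type 2 and -0.01 without knockout 3), while fry's test for change in either direction gave an adjusted p of 0.000600. Dystroglycan (Dag1) differed by -0.16, and the sarcoglycan genes Sgca, Sgcb and Sgcd by -0.02, -0.14 and -0.14. Sgca changed sign in 5 of 20 alternatives, and Sgcd differed by -0.06 without wild type 2. The dystrophin homologue Utrn measured 6.81 ± 0.16 in wild type and 6.72 ± 0.09 in knockout (limma adjusted p = 0.930).

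Of 44 gene lists fixed beforehand, 10 passed a 5% false discovery rate in camera with a preset correlation between genes of 0.01, 5 up and 5 down. With the correlation estimated from the data 0 of the 10 passed, and 0 passed in fry's one-direction test. Among the 35 ways to divide the 8 arrays into 4 and 4, 17 gave at least 10 lists. An exact permutation test of each list's mean per array gave no adjusted value under 0.251. It can give no p below 0.0286, so it could hardly pass when adjusted over 44 lists and decides nothing here. Before adjustment the macrophage, immediate-early, endoplasmic reticulum chaperone, erythroid and myokine lists reached that floor. Since 0 lists passed with an estimated correlation or in fry's one-direction test, the directions given next are those of camera alone.

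Macrophage markers were the list with the smallest p. Of 22 measured genes 21 were higher in knockout, by a mean of 0.32 (camera adjusted p = 7.49e-11; adjusted p = 0.293 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. The list mean was 5.39 to 5.53 in the wild types and 5.62, 5.57, 5.76 and 6.09 in knockouts 1 to 4. Tyrobp, a signalling adaptor of myeloid cells, measured 5.21 ± 0.18 in wild type and 5.86 ± 0.44 in knockout. C1qb, a chain of complement C1q, differed by 0.42. The rise was uneven between genes. In knockout 4 Gpnmb measured 9.09, Lgals3 7.75 and Cd68 7.35, against wild-type means of 5.34, 5.88 and 5.56. Cd163 (4.22) and Pf4 (5.67) lay below every wild type in that array. Without knockout 4 the mean shift of the list was 0.21. Markers of erythroid cells were also higher (5 of 6 genes, mean 0.17, camera adjusted p = 0.0204; adjusted p = 0.364 with an estimated correlation), with Car2 at 0.40 and Bpgm at 0.28. That list did not pass without knockout 2 (mean 0.15, camera adjusted p = 0.101), and only 6 of its 12 entries were measured.

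Genes of the immediate-early response, which cells induce within minutes of a stimulus, were lower in knockout. Of 24 measured genes 22 were lower, by a mean of -0.19 (camera adjusted p = 7.37e-05; adjusted p = 0.457 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 5 passed: Jun, Fos, Nr4a1 and Nr4a2 lower and Myc higher. Jun, a subunit of the transcription factor AP-1, measured 8.53 ± 0.08 in wild type and 7.86 ± 0.18 in knockout, Fos differed by -0.38, and Myc by 0.47. Chaperones of the heat-shock response were lower in 17 of 20 cases (mean -0.15, camera adjusted p = 0.00131; adjusted p = 0.457 with an estimated correlation). Hspa1a, Hspb1 and Hsp90aa1 passed adjusted over the list alone, with differences of -0.54, -0.40 and -0.36, and 0 passed over all genes. In fry's test for change in either direction the immediate-early list had an adjusted p of 0.0459 and the heat-shock list 0.0543. Chaperones of the endoplasmic reticulum were lower in 21 of 24 cases (mean -0.09, camera adjusted p = 0.00888; adjusted p = 0.364 with an estimated correlation), and Hspa5, the reticulum's main Hsp70 protein, differed by -0.25. The macrophage list moved in the opposite direction in the same knockouts, by 0.32.

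Fatty acid uptake and oxidation genes were higher in 23 of 27 cases (mean 0.09, camera adjusted p = 0.00368, adjusted p = 0.989 with an estimated correlation). Cpt1a, the liver-type carnitine palmitoyltransferase, differed by 0.23 and Plin5 by 0.36. The Plin5 difference was 0.17 without wild type 2, where it measured 4.95. The list's call was lost without wild type 1 (mean 0.03), knockout 2 (0.03) or knockout 3 (0.00433). Its mean was 0.15 without knockout 1 and 0.18 without knockout 4. The list stood highest in knockouts 2 and 3 (8.70 and 8.79), where the slow-fibre list was also highest (8.56 and 8.76), and at 8.25 in knockout 4, where the slow-fibre list was lowest (6.33). With the slow-fibre level as covariate the fatty acid list still passed (mean 0.10, camera adjusted p = 0.000163). The slow-fibre mean differed by only -0.03 between genotypes, opposite in sign to the fatty acid shift, so this covariate could hardly move the difference. Over all 8 arrays these values argue against the measured slow-fibre level as the source of the mean shift. They do not show that the shift itself is real. The correlation between the list's genes was estimated at 0.69, against the preset 0.01, and with that estimate the list did not pass. Cholesterol and lipid synthesis genes were lower in 21 of 25 cases (mean -0.11, camera adjusted p = 0.00888; adjusted p = 0.457 with an estimated correlation), with the fatty acid elongase Elovl6 at -0.34 and Acly at -0.21. Over all genes and adjusted over the list alone, 0 members of either list passed. Genes of the cytosolic ribosome were higher in 20 of 28 cases (mean 0.06, camera adjusted p = 0.00888; adjusted p = 0.989 with an estimated correlation), and Rps19 passed adjusted over the list alone (difference 0.35). Without wild type 3 or knockout 4 the mean was 0.04 and the list did not pass (camera adjusted p = 0.214 and 0.0919). A second ribosomal gene, Rps9, differed by 0.28 in the transcript cluster used and by -0.06 in its other cluster.

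Embryonic and regenerating fibre genes were higher in 15 of 22 cases (mean 0.15, median 0.04, camera adjusted p = 0.0381; adjusted p = 0.457 with an estimated correlation), and Actc1 was the member that passed adjusted over the list alone. The list passed in 9 of 23 alternatives, and not without wild type 2 (mean 0.14), wild type 4 (0.14), knockout 1 (0.15), knockout 3 (0.13) or knockout 4 (0.11). Schwann cell and nerve genes were lower in 11 of 15 cases (mean -0.18, camera adjusted p = 0.0482; adjusted p = 0.989 with an estimated correlation), with 0 members past either adjustment and Ncmap at -0.57. That list also passed in 9 of 23 alternatives. Its mean was -0.05 without wild type 3 (camera adjusted p = 0.767) and -0.30 without wild type 2, and it did not pass without wild type 1 (-0.22), wild type 4 (-0.15), knockout 1 (-0.18), knockout 2 (-0.15) or knockout 4 (-0.13) either.

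**Figure D3:**
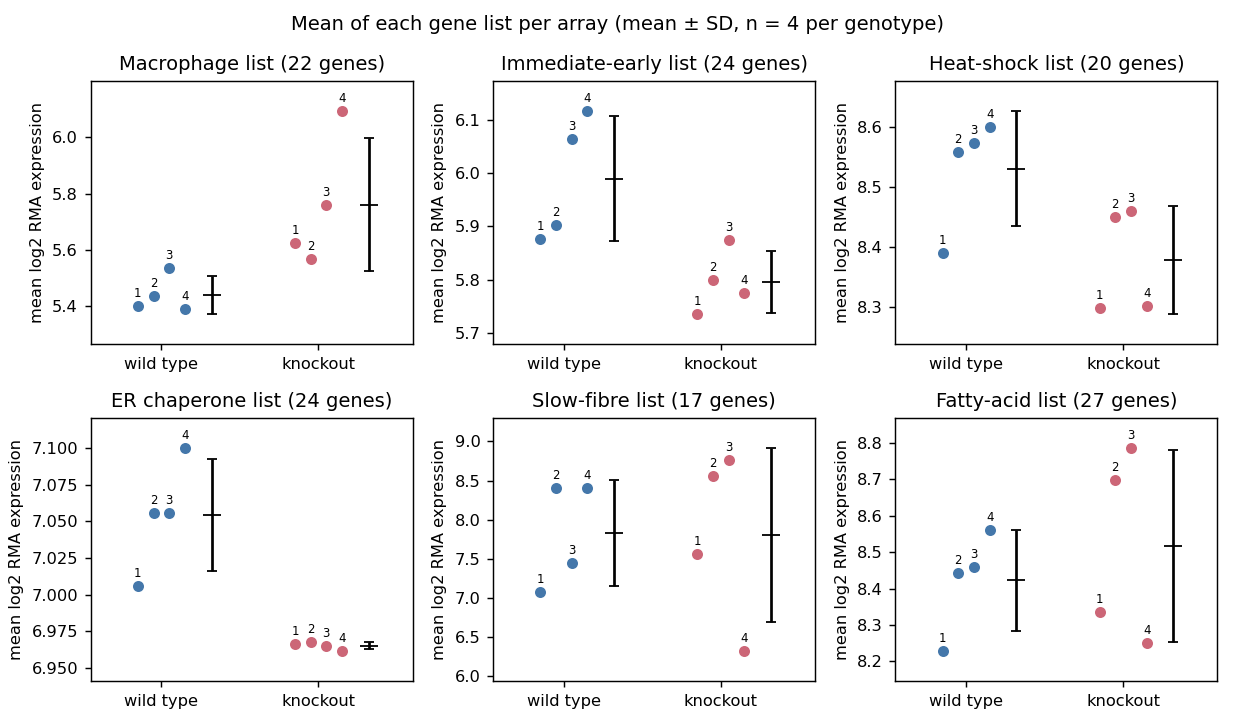
Mean log2 RMA expression of 6 gene lists in each array, with blue points for wild type, red points for knockout, the replicate number above each point and bars for mean ± SD (n = 4 each). The macrophage list lies higher in all knockouts than in all wild types (6.09 in knockout 4), and the slow-fibre list spreads from 6.33 to 8.76 without separating the genotypes. Vertical axes differ between panels and do not start at 0.

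Mitochondrial and regulatory lists were also tested in camera. Complex I genes had a mean difference of 0.02 (adjusted p = 0.349), complexes II to V 0.01 (0.349), the tricarboxylic acid cycle 0.04 (0.0962), mitochondrial ribosome and import 0.01 (0.525) and branched-chain amino acid breakdown 0.02 (0.349). These 5 lists missed the threshold there but passed in 4, 5, 9, 2 and 4 of 23 alternatives, in that order. With array weights all of them passed (means 0.07, 0.06, 0.09, 0.04 and 0.08), as they did without wild type 2 (0.06, 0.04, 0.07, 0.03 and 0.07). Complexes II to V also passed without wild type 4 (0.04), and the tricarboxylic acid cycle without wild type 4 (0.06), knockout 1 (0.07) or knockout 4 (0.08). The same 5 means were below 0 without wild type 1 (-0.02, -0.04, -0.00179, -0.02 and -0.02). So were complex I, complexes II to V and branched-chain breakdown without knockout 2 (-0.00233, -0.00372 and -0.000595), complexes II to V without knockout 3 (-0.01) and mitochondrial ribosome and import without wild type 3 (-0.01). The list of PGC-1 and PPAR regulators had a mean of -0.07 (0.586), which was -0.03 without knockout 4, -0.04 without knockout 1 and -0.10 without knockout 3. Ppargc1a, whose product PGC-1alpha is a known acetylation substrate of Gcn5, measured 9.10 ± 0.31 in wild type and 8.76 ± 0.29 in knockout (limma adjusted p = 0.869). Other subunits of SAGA and ATAC had a mean of -0.04 (0.441), other acetyltransferases and deacetylases -0.02 (0.912) and histone genes -0.04 (0.711). Without wild type 2 these 3 means were 0.00702, 0.02 and 0.000589, and that of the acetyltransferases and deacetylases was 0.00170 without knockout 3. Yy1, a transcription factor gene, differed by -0.08 (limma adjusted p = 0.925).

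Contractile and cell-type lists were measured in the same way. Slow-fibre genes had a mean of -0.03 (adjusted p = 0.576), which single arrays decided: the list passed as lower without knockout 2 (-0.28) or knockout 3 (-0.35) and as higher without knockout 4 (0.46), without wild type 2 and knockout 4 together (0.65) or with the macrophage level as covariate (1.12). It was above 0 without passing when wild type 2 (0.16), wild type 4 (0.16) or knockout 1 (0.05) was left out. The macrophage level was higher in every knockout than in every wild type. Fits with it as covariate therefore separate it poorly from genotype, for every list. Knockout 4 had both the highest macrophage mean (6.09) and the lowest slow-fibre mean (6.33). Fast-fibre genes had a mean of -0.04 (0.976), Z-disc and costamere genes -0.10 (0.586), calcium handling -0.04 (0.291) and denervation and neuromuscular junction -0.08 (0.281). Without wild type 2 the means were -0.02 for fast-fibre genes and 0.00872 for calcium handling, and without knockout 4 the Z-disc mean was -0.02. The denervation mean was -0.05 without wild type 4. In the denervation list Musk, the receptor kinase of the neuromuscular junction, measured 8.43 ± 0.42 in wild type and 7.68 ± 0.33 in knockout (limma adjusted p = 0.538). Endothelial genes had a mean of -0.08 (0.228), smooth muscle and pericytes -0.01 (0.997), fibro-adipogenic progenitors -0.01 (0.977), adipocytes -0.07 (0.711), tendon 0.03 (0.586) and lymphocytes and neutrophils -0.06 (0.349). Endothelial genes passed without wild type 1 (-0.13) or knockout 2 (-0.16), tendon without knockout 4 (0.16) and lymphocytes and neutrophils without wild type 2 (-0.09). The endothelial mean was nearer 0 without wild type 4 (-0.03), knockout 1 (-0.03) or knockout 4 (-0.04). Adipocytes and tendon passed without wild type 2 and knockout 4 together (-0.26 and 0.19) and with the macrophage level as covariate (-0.29 and 0.33). Tendon was below 0 without wild type 4 (-0.03), knockout 2 (-0.11) or knockout 3 (-0.03), and adipocytes above 0 without knockout 1 (0.03). Smooth muscle and progenitors were above 0 without wild type 3 (0.06 and 0.00529) or knockout 4 (0.00346 and 0.02), and smooth muscle also without wild type 4 (0.00561).

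Matrix, stress and signalling lists gave the following camera results. Basement membrane had a mean of -0.03 (adjusted p = 0.711), extracellular matrix and fibrosis -0.01 (0.976; 0.08 and past the threshold with the macrophage level as covariate), interferon and MHC 0.00168 (0.711), inflammatory cytokines 0.00521 (0.711), antioxidant NRF2 targets 0.05 (0.291), the ATF4 response -0.00965 (0.976) and p53 targets -0.03 (0.977). In the NRF2 list the glutathione transferase gene Gsta4 passed adjusted over the list alone (difference 0.40). Autophagy and lysosome had a mean of -0.03 (0.546), atrophy and the proteasome -0.02 (0.976), myokines and growth signalling -0.08 (0.128), the circadian clock -0.05 (0.349), proliferation -0.01 (0.976) and glycolysis and glycogen -0.03 (0.940). Leaving out 1 array changed the size of some of these means and the sign of several. Basement membrane was -0.003 without wild type 4 and -0.07 without knockout 2. Autophagy and lysosome was -0.008 without wild type 2 and -0.06 without knockout 4. The sign changed in the following cases. Without wild type 2 interferon was -0.04, inflammatory cytokines -0.06, p53 targets 0.01, atrophy 0.00781 and the clock 0.000635. Without wild type 4 inflammatory cytokines were -0.00152, the matrix 0.00127 and proliferation 0.00692. The matrix was also above 0 without wild type 3 (0.03), knockout 1 (0.01) or knockout 4 (0.04) and atrophy without knockout 2 (0.00175), and interferon was below 0 without wild type 1 (-0.00147), knockout 1 (-0.02) or knockout 3 (-0.03). The mean and median differed in sign for the glycolysis, matrix, ATF4, interferon and inflammatory lists, and camera's direction opposed the mean for the matrix, ATF4, fast-fibre and smooth muscle lists.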

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

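The tests of the macrophage list, of fibre genes against Dmd, with the slow-fibre covariate, and of the counts at an adjusted p under 0.10 and an unadjusted p under 0.01 were chosen after the results were seen. The neighbour test of Lrtm1 and Ssbp2 was also written down after the results were seen. Its division into 1 result per gene, the margin around its limit and the rule that dim lists decide nothing were set after its values were known.

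The first pattern is the small set of called genes. Among the 35 divisions of the 8 arrays, 4 gave at least 1 gene in a direction and 3 gave at least 2 (highest other 5), so chance cannot be excluded for the counts of 1 higher and 2 lower genes, which says nothing against Kat2a, the deleted gene and 1 of the lower ones (difference -0.66, SE 0.08, groups apart); the division with 5 set the 4 arrays with the lowest slow-fibre list means against the rest, and with the slow-fibre level as a covariate 1 gene was higher and 3 were lower, of which 2 (Kat2a and Lrtm1) were called without it, while Ssbp2 no longer passed (limma adjusted p = 0.0585; difference -0.69 in both, SE 0.09 without and 0.10 with the covariate). At an adjusted p under 0.10, 1 division, the real one, gave 16 genes (highest other 7). This is the smallest result that 35 divisions can give, and the test was added after the results were seen. The 16 genes also include Kat2a, so the count argues only weakly against chance for that set. It was 12, 2, 7 and 0 without wild types 1 to 4 and 0, 4, 0 and 5 without knockouts 1 to 4. At an unadjusted p under 0.01, 7 divisions gave at least the 244 genes seen (highest other 458). A chromosome segment that differs between the genotypes could shift neighbouring genes too. The 10 tested genes on each side of Ssbp2 stood at the 34.9 percentile of median absolute t. This argues against a segment that shifts most of them, but one that shifts few would leave the median unmoved. The genes around Lrtm1 stood at 92.1, under the limit of the 95th percentile but too near it to decide. An effect of Gcn5 loss and an effect of Cre itself stay open for both genes.

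The second pattern is the lower Dmd signal. Under 3 other normalizations the difference was -0.57 or further from 0. The deposited values had already been normalized by quantiles, so these normalizations could hardly move it and decide little. The median difference over all genes was -0.014, which argues against a shift of whole arrays as the source. A lower share of fibre RNA would lower fibre genes alike, and 74 genes of the Z-disc, calcium and fast sarcomere lists had a median difference of -0.0290, against -0.61 for Dmd. As a hypothesis, Dmd transcript may be lower in fibres that lack Gcn5; the gene missed the threshold, and Cre was present in knockouts alone, so neither point is settled.

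The third pattern is the higher macrophage list, one of the 10 lists past the test. For the number of lists chance cannot be excluded, since 17 of the 35 divisions gave at least 10 (highest other 22). Knockout 4 alone does not account for it, since without that array the mean difference was 0.21 and knockouts 1 to 3 (lowest 5.57) stayed above all wild types (highest 5.53), although by little. A lower share of fibre RNA would raise other cell types too, and 4 lists of other non-fibre cells had a median difference of -0.0476 (SE 0.09 for their joint mean). Blood leukocytes left in the tissue cannot be told apart. The lymphocyte and neutrophil list (difference -0.0614) had a mean level of 3.44, too dim against an all-gene median of 4.99. The erythroid list was higher in every knockout (lowest 5.85) than in every wild type (highest 5.82), as more blood in the tissue would give. Its difference was 0.17 (0.15 and short of the threshold without knockout 2). Only 6 of the list's 12 entries were measured. Car2 and Bpgm, the 2 with an unadjusted limma p under 0.05, each overlapped between genotypes. The list therefore does not settle how much blood the tissue held. Of the 22 macrophage genes 0 stood in another list. More macrophages in knockout muscle remain a possible explanation, although Cd163 and Pf4 lay below every wild type in knockout 4.

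Values of single arrays that stood far from the other 3 of their group were found in 20 of 300 groups examined, where chance gives about 15. Among named genes in knockouts these were Ssbp2 at 7.72, Irf1 at 5.58, Pdk4 at 11.84 and Pdp1 at 9.11 in knockout 3, Vmn1r58 at 3.02 and Nefl at 3.33 in knockout 4, and Zfp706 at 9.26 in knockout 1. In wild types they were Ugp2 at 10.39, Plin5 at 4.95, Kat5 at 6.65 and H4c9 at 5.44 in wild type 2, Acly at 5.64 and Pdk4 at 11.40 in wild type 1, and Bpgm at 6.36, Dag1 at 8.71 and Atp5j2 at 10.21 in wild type 4. Among list means they were the PGC-1 and PPAR regulators at 7.01 in wild type 1, atrophy and proteasome at 7.88 in knockout 2, autophagy and lysosome at 7.94 in knockout 4 and the ATF4 response at 6.19 in knockout 3.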

How the results depend on the processing

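Leaving out wild type 2 and knockout 4 together, and both covariates, were chosen after the data were seen. No result changed direction among the called genes and lists. Kat2a kept a difference between -0.68 and -0.60 and passed in 11 of 21 alternatives (adjusted p from 0.00916 to 0.724). Leaving out 1 array gave 0 to 2 higher genes, 0 to 3 lower genes, 8 to 15 lists and Kat2a differences from -0.68 to -0.64. Higher and lower genes numbered 1 and 1 with quantile normalization or cyclic loess, 1 and 10 without the dimmest 25% of genes, 3 and 10 without the dimmest 50% (fewer genes tested), 3 and 14 with an intensity trend and robust prior, 0 and 0 over all deposited clusters (more tests; Kat2a -0.66, adjusted p = 0.0660), 3 and 13 at an adjusted p under 0.10, 96 and 148 at an unadjusted p under 0.01 and 0 and 0 in limma's treat (1142 genes at an unadjusted p under 0.05 in limma). Without wild type 2 and knockout 4 there were 1 and 0 (Kat2a -0.64, adjusted p = 0.135; fewer arrays). With the macrophage level as covariate there were 0 and 0 (Kat2a -0.60, adjusted p = 0.724); that level separates the genotypes. With the replicate block there were 0 and 0, with Kat2a at -0.66 (limma adjusted p = 0.113). Deviations from the group means correlated at 0.0939, 0.0655, 0.222 and -0.103 between same-numbered arrays. Between arrays of different numbers they correlated at -0.234 to 0.122. These values show no clear pairing but cannot exclude one, and the labels do not say whether the numbers pair animals. Lists numbered 0 with an estimated correlation, 0 in fry and 8 to 15 otherwise. Other causes were not tested. Dim transcripts limit what low signals can show.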

Other observations

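The handling test and the Actc1 test were chosen, or their limits set, after the results were seen.

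Slow-fibre genes varied more between animals than any other of the 44 lists, with a pooled SD of the list mean of 0.92 against 0.28 for the next, tendon. Myh7, the slow myosin heavy chain, ranged from 5.21 in knockout 4 to 9.24 in knockout 3 and from 5.33 to 8.92 among wild types. Knockout 4 also stood apart in genes chosen after their values were seen: Gpnmb measured 9.09 there and a mean of 5.81 in the other knockouts, Mmp12 7.62 and 4.37, and Atp6v0d2, a subunit of the lysosomal proton pump, 6.04 and 2.64. Gpnmb belongs to the macrophage list, as do Lgals3 and Cd68, which measured 7.75 and 7.35 in knockout 4 against means of 6.19 and 5.87. Actc1 was highest in the same array, at 11.27 against a mean of 9.83.

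Actc1 is also made in regenerating fibres, which was tested as a hypothesis for its higher level in knockout. Myh3, Myh8, Myog, Mymk, Chrng and Myl4 had a median difference of 0.0575 (SE 0.07 for their mean), which argues against fibres that raise all 6 as far as the 1.79 of Actc1. The mean level of the 6 genes was 5.28, above the all-gene median of 4.99, but Myh3, Myog and Chrng lay under it (4.22, 3.97 and 4.75 in wild type), so smaller changes stay open. Handling at dissection could set the level of immediate-early genes: 8 fast-induced genes (Fos, Fosb, Egr1, Egr3, Ier2, Dusp1, Zfp36 and Junb) had a median difference of -0.0881, with Junb at 0.04 and Dusp1 at -0.39, which does not decide between handling and genotype.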
